A study of Mus musculus with 24 samples.

How the data were processed

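The libraries were poly(A)-selected and stranded (TruSeq Stranded mRNA), per the labels' protocols, and cover 6 samples of dissected cortex and 18 of cultured cortical neural stem cells. For the cortex the authors deposited a table of whole-number counts per gene. Per the submitters' processing notes the reads were aligned with HISAT2 and counted with featureCounts, and per the file headers the counter was version 1.5.0-p2, run on paired and stranded reads against GENCODE vM16. For the cultures the authors deposited estimated counts per transcript made with kallisto 0.43.0, per the submitters' processing notes, which also name GRCm38.p5. The deposited culture tables carry further columns in other units (transcript length and effective length), and their deposited effective lengths were used only for a length offset. The annotation release behind the kallisto index is not given in the sources used here. The deposited count table of the cortex holds 53379 genes, and the culture tables hold 136529 transcripts, which were summed to 54144 genes. Lines without values, 6 in each culture table, were not used here. Both tables share 53333 gene IDs. Gene symbols were taken from the reference annotation of GRCm38 by gene ID, which named 53274 cortex and 54077 culture genes. Pnky carries the symbol Gm30731 there and was found through its listed synonym Pnky.

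Estimated counts were summed over the transcripts of each gene and rounded to whole numbers. Depth was 59255443 to 68803051 counts per cortex library and 68877807 to 82558559 estimated counts per culture library. In the cortex table all 37 mitochondrially encoded genes stand at 0 in every library, whereas they took 5.27 to 7.68% of the counts in cultures, so these genes were compared in cultures only and levels were not compared across the tables. The symbol Aldoa carries 2 gene IDs in the reference, and both were kept in the hypoxia list. Strand-specific counting separates Pnky from antisense reads in the cortex. How kallisto treated strand is not given in the sources used here, and kallisto divides reads shared between near-identical transcripts by estimate. No pair of libraries held identical values (0 of 168 pairs compared within a table), and every pair differed by more than sampling noise (smallest chi-square of 13.1 per gene).

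Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F-test, 2-sided, R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The cortex fit used the 6 cortex libraries with no block. The culture fits used all 18 culture libraries, with culture number nested in genotype and an Ad:Cre effect within each genotype, because the series describes group-specific condition effects, and the differences between genotypes are contrasts of these effects. The untreated comparisons used all 18 libraries in 6 groups with no block. CPM values are based on TMM-scaled library sizes. The 32 gene lists, covering cortical cell types, other cell types a dissection or culture could hold, the cell cycle, stress and signalling pathways, the neighbourhood of Pou3f2 and sex-linked genes, were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, for lists with at least 5 tested genes and with Benjamini-Hochberg adjustment per comparison. With an estimated correlation 0 lists passed in any of the 9 comparisons, and each such adjusted p is given beside its list. The tests, the lists and the rule for named genes were fixed before the data were examined.

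In every comparison the text names Pnky and Pou3f2, and passing genes of the Pou3f2 neighbourhood are eligible. Among genes past the threshold with a mean of at least 2 CPM it takes the 8 largest rises and the 8 largest falls (5 and 5 for BAC against FF or WT, 4 and 4 for untreated cultures). Predicted genes and pseudogenes are counted but not named. Where fewer than 10 genes pass, the 5 higher and 5 lower genes with the smallest p are given as not passing. From each list that passes, or with at least 3 passing members, up to 4 members with the smallest adjusted p are eligible, and the text gives a selection of these. A few genes that are eligible by these rules are not reported here.

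The cortex replicates pair by litter, as the labels state, and deviations from group means correlated by 0.376, 0.134 and 0.137 within the 3 litters. In cultures the treated and untreated libraries of 1 number correlated by 0.148 to 0.317 in each genotype, each best with its own number, so the nested block was kept. Untreated cultures of different genotypes correlated little by number (from -0.0164 to 0.120), so numbers were not used to pair them. After Ad:Cre, however, mitochondrial shares in number 3 were 6.805, 6.853 and 6.812% in BAC, FF and WT, against 7.38 to 7.68% in numbers 1 and 2. A batch shared by number across genotypes was thus not excluded, and its effect on the Ad:Cre differences was not tested. Sex was read from Xist and Ddx3y. It was female in 3 cKO embryos and in 1 of 3 controls, and in 2 WT, 1 FF and 1 BAC culture of 3 each.

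The scripts were tested on simulated data with 200 of the genes changed by known folds, 50 of them at each fold size, the smallest a log2 fold change of 0.32. For cortex, 4% of genes were recovered at this size and 66, 82 and 100% of genes changed 1.5-, 2- and 4-fold, with 15 false among 141 calls. For the Ad:Cre effect in FF the shares were 64, 82, 92 and 100%, with 17 false among 186 calls, and for FF against WT they were 24, 64, 70 and 96%, with 12 false among 139 calls. The false share was thus above the nominal level in these simulations. The changed genes were drawn from those with a mean above 50 counts, and the noise was independent between genes. Recovery of genes with fewer counts was thus not measured. Alternatives were DESeq2 1.42.0 as the test, its size factors within edgeR, no filter on low counts, the fit with or without the block, average transcript length as an offset, the 6 libraries of a genotype alone, and leaving out each library in turn. Sex as a covariate was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.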

Results

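RNA sequencing was carried out on 24 libraries from C57BL/6 mice, in 8 groups of 3. The 6 cortex libraries came from tissue dissected at embryonic day 12.5. They comprised 3 conditional knockouts (cKO), in which Emx1-Cre, a recombinase active in progenitors of the dorsal forebrain, acts on a floxed Pnky gene, and 3 controls. The labels place 1 cKO and 1 control in each of litters 1, 2 and 5. The other 18 libraries came from cortical neural stem cells of the same embryonic age, cultured with EGF and FGF. The cells were wild type (WT), homozygous for the floxed Pnky gene (FF), or floxed and carrying Pnky on a bacterial artificial chromosome transgene (BAC), and each genotype was left untreated or given an adenovirus carrying Cre (Ad:Cre) and cultured for 3 days. Total counts ran from 59255443 to 68803051 per cortex library and from 68877807 to 82558559 per culture library. The series describes the replicates as biological, but the labels do not tie a culture number to an animal, so p-values for the cultures measure only the spread between these samples.

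Pnky, the long noncoding RNA targeted here (ENSMUSG00000107859), lies on chromosome 4 of GRCm38 at 22490548 to 22493126 on the plus strand, with 3 exons of 236, 309 and 280 bp. It is next to Pou3f2 (ENSMUSG00000095139, 22482780 to 22488366, minus strand), which encodes a POU-domain transcription factor of neural progenitors and neurons. In cultures Pnky stood at 4.40 ± 0.333 CPM (counts scaled to library size, SD, n = 3) in untreated FF libraries and at 0.0450 ± 0.0423 CPM after Ad:Cre, where it had 1 to 7 counts per library. This was 1.02% of the untreated level. BAC cultures went from 4.63 ± 0.783 to 0.603 ± 0.112 CPM, 13.0% of untreated, and WT cultures from 4.45 ± 0.501 to 2.79 ± 0.284 CPM, 62.8% of untreated. After Ad:Cre, Pnky in BAC cultures was thus at 21.6% of its level in WT cultures. The log2 fold changes were -6.55 (SE 0.27) in FF, -2.93 (SE 0.17) in BAC and -0.67 (SE 0.15) in WT, with adjusted p = 8.19e-10, 1.04e-08 and 0.00144 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In dissected cortex Pnky stood at 1.20 ± 0.435 CPM in controls and 0.835 ± 0.0862 CPM in cKO embryos (n = 3 each), 69.3% of control. The cortex log2 fold change of -0.53 (SE 0.27) did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 1.00), although the cKO value was the lower one in 3 of 3 litters. Without control 1 it was -0.22. The part of Pnky removed by recombination is not given in the sources used here, and reads from any part that remains would be counted. In FF cultures, however, the floxed gene left 1.02% of untreated Pnky after Ad:Cre. This argues against remaining parts as the main source of Pnky reads in cKO cortex, although cortex reads were counted by another method. How much of the dissected tissue was recombined is not given in the labels.

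**Figure D1:**
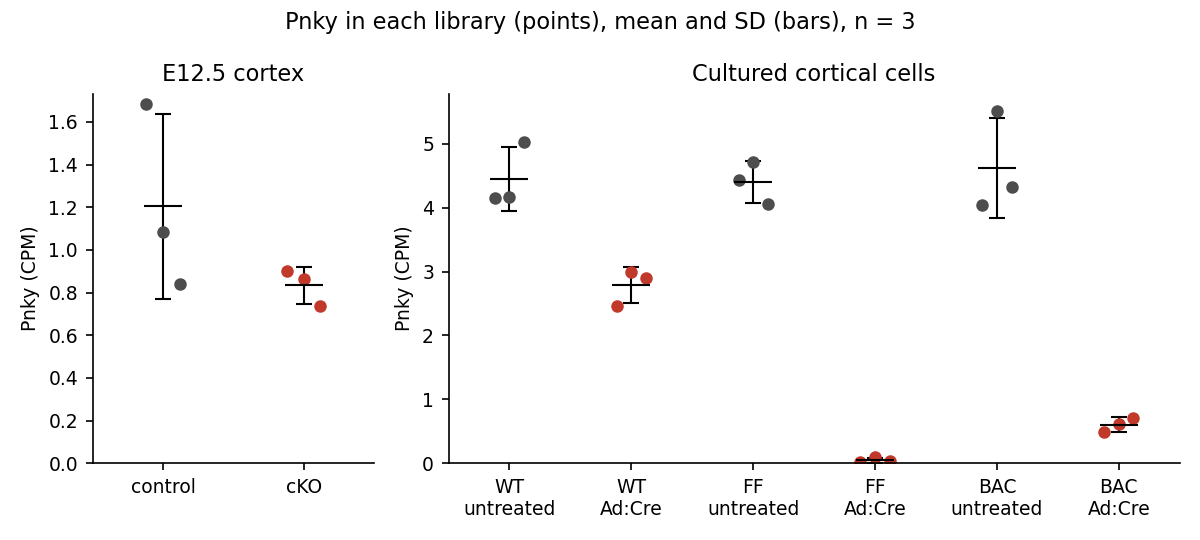
Pnky in CPM (vertical axes) in each library of the cortex and culture groups, with the mean and SD of 3 libraries per group as bars. FF cultures after Ad:Cre averaged 0.0450 CPM, against 0.603 in BAC and 2.79 in WT cultures, while cKO cortex averaged 0.835 against 1.20 in controls.

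The cortex comparison asked which genes differ in the developing cortex when Emx1-Cre acts on the floxed Pnky gene. Genes of microglia and macrophages, the resident and invading phagocytes of the brain, were the clearest group. P2ry13, a purinergic receptor of microglia, had a log2 difference of 1.27 (SE 0.21), Trem2, a phagocyte receptor, 1.16 (SE 0.21), and C1qb and C1qc, subunits of complement C1q, 0.81 (SE 0.12) and 0.82 between 3 cKO and 3 control embryos. None of these genes passed edgeR's test over all genes tested. DESeq2's Wald test called each of them (adjusted p = 0.0484 for P2ry13, 0.0473 for Trem2, 2.43e-04 for C1qb and 0.00201 for C1qc). Of 14 microglia and macrophage genes measured, 12 were higher when adjusted over the list alone, the median log2 difference was 0.78, and the list passed camera's test against all other genes (adjusted p = 8.26e-29). That call was lost with adjusted p = 0.0998 with an estimated correlation. Genes of the subpallium, the source of cortical interneurons, lay lower. Dlx1, a homeobox gene of that lineage, had a log2 difference of -2.17 (SE 0.47) and Dlx2 one of -0.70, and 1 of the 6 measured list genes, Dlx1, was lower adjusted over the list alone. The subpallial list passed camera's test with a median of -0.36 (adjusted p = 0.00150, and adjusted p = 0.255 with an estimated correlation).

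Smaller shifts were spread over whole lists in the cortex, with no single member passing over all genes or over the list alone. Targets of p53, the damage-responsive transcription factor, had a median of 0.11 over 18 genes (camera adjusted p = 2.20e-05, and adjusted p = 0.0998 with an estimated correlation), with Eda2r at 0.67 and Pmaip1 at 0.63. Eda2r lies on the X chromosome, and all cKO embryos were female while 2 controls were male. Pmaip1 stood low, at 0.626 CPM in controls and 0.972 in cKO embryos. Bax, at 46.1 CPM in controls, had 0.18. The 18 S phase genes had a median of 0.06 (camera adjusted p = 0.00153, and adjusted p = 0.965 with an estimated correlation). Erythroid genes had a median of 0.12 and a mean of 0.04 (camera adjusted p = 0.0159, and adjusted p = 0.994 with an estimated correlation), led by Hba-a2, an alpha-globin gene, at 0.46. This erythroid call rested on control 1, without which the camera adjusted p was 0.371 and the direction turned. Notch pathway genes had a median of -0.06 (camera adjusted p = 0.0175, and adjusted p = 0.965 with an estimated correlation), and Wnt targets one of -0.16 (camera adjusted p = 0.0223, and adjusted p = 0.994 with an estimated correlation), with Apcdd1 at -0.49. Genes of the cortical hem and choroid plexus had a median of -0.22 and missed the threshold (camera adjusted p = 0.0625), but passed with litter as a block (adjusted p = 0.00144). The other 23 lists with enough measured genes did not pass. Among them radial glia (median -0.03, camera adjusted p = 0.910), intermediate progenitors (-0.05, 0.789), postmitotic neurons (-0.03, 0.986), deep-layer neurons (-0.02, 0.789) and upper-layer neurons (-0.06, 0.988) bear on the cell types of the early cortex. The deep-layer and upper-layer lists had positive means and a positive test direction beside their negative medians. Surface ectoderm genes, from skin that a dissection can carry, had a median of 0.42 and a mean of 0.07 beside a negative test direction (camera adjusted p = 0.757).

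Over all genes, 0 of 17415 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in the cortex (smallest adjusted p = 1.00). At an unadjusted p under 0.05 there were 385 genes, where 870.75 would be reached with no effect and independent genes. DESeq2 called 20 genes, 13 higher and 7 lower. Of its higher genes 6 are on the microglia list, among them C1qb, C1qc and Cx3cr1, a chemokine receptor of microglia, and its lower genes include Kdm5d, Uty, Eif2s3y and Ddx3y, which lie on the Y chromosome. By Xist and Ddx3y the 3 cKO embryos were female, and so was 1 of the 3 controls. The lower genes with the smallest p in edgeR besides Dlx1, none passing its test, were Pax7 (-2.13), Grhl3 (-1.17), Tle2 (-0.55) and Prmt8 (-0.54). Of these DESeq2's Wald test called Pax7, Grhl3 and Prmt8 (adjusted p = 0.00662, 0.0159 and 0.0484). Ctsd, a lysosomal protease, had 0.32 and was called by DESeq2 only (adjusted p = 0.0144). Pou3f2 had a log2 difference of 0.54 (SE 0.34) that did not pass (0.22 without control 3 and 1.04 without control 1, neither passing), and the list of its neighbours on chromosome 4 had a mean of 0.03 over 15 genes (camera adjusted p = 0.972). Without control 1 edgeR called 1 gene and without control 2 it called 7, and with no filter on low counts it called 7 (1 higher, 6 lower). At these depths a simulation recovered 66% of genes changed 1.5-fold and 82% of those changed 2-fold in this comparison. Its changed genes were drawn only above a floor of mean counts, and its noise was independent between genes. Recovery in these libraries can therefore be lower, and it was not measured for genes with few counts.

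**Figure D2:**
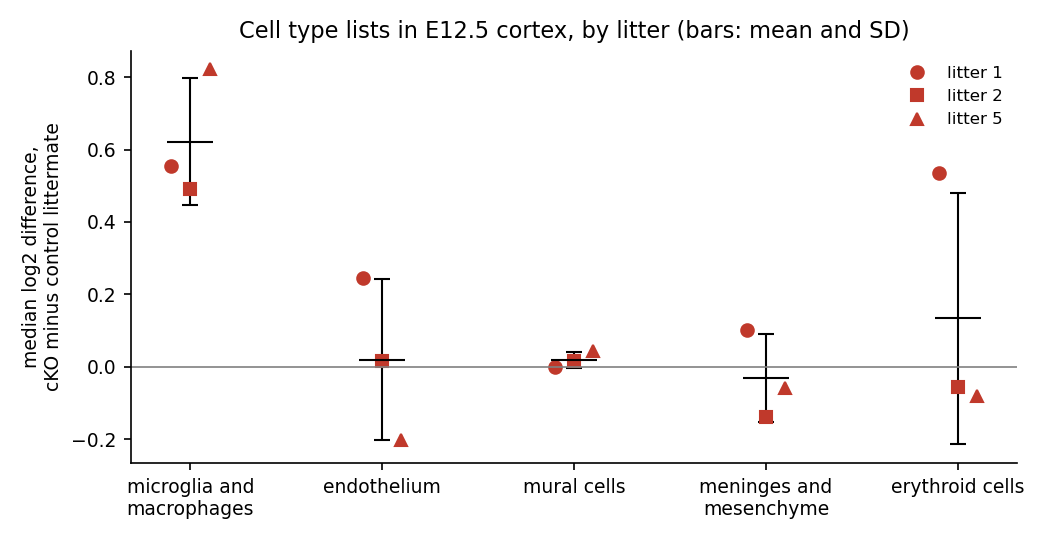
Median log2 difference between cKO and control littermate (vertical axis) over the genes of 5 cell type lists, with a point per litter and the mean and SD over 3 litters as bars. The microglia and macrophage medians were 0.55, 0.49 and 0.82 in litters 1, 2 and 5, while those of mural cells averaged 0.02.

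In WT cultures, which carry no floxed allele, Ad:Cre shows the joint effect of virus, Cre and any other difference in handling from untreated cultures. No group was given virus without Cre, so these cannot be told apart. Cell cycle genes rose together. Mcm3, a subunit of the replicative helicase, rose by a log2 fold change of 2.50 (SE 0.07) and Ccnd1, the G1 cyclin D1, by 2.98 (SE 0.09; n = 3 against 3). Of 18 S phase genes all 18 rose, with a median of 2.05 (camera adjusted p = 1.86e-13, and adjusted p = 0.431 with an estimated correlation). Of 20 genes of G2 and M phase all 20 rose, among them the kinase Cdk1 at 1.41, with a median of 1.31 (camera adjusted p = 1.79e-06, and adjusted p = 0.589 with an estimated correlation). Of 20 p53 targets 19 rose, with a median of 0.88 (camera adjusted p = 6.04e-11, and adjusted p = 0.431 with an estimated correlation), among them Perp at 2.52, the kinase Plk2 at 1.63 and Mdm2, the ubiquitin ligase that restrains p53, at 0.91. Feedback genes of growth factor and ERK signalling rose in 11 of 14 cases, with Dusp6 at 1.61 and Spry1 at 1.34 (camera adjusted p = 8.04e-04, and adjusted p = 0.589 with an estimated correlation). Adjusted over the list alone, the counts of rising genes in these 4 lists were again 18, 20, 19 and 11.

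Other groups fell in WT cultures. Of 20 genes of cholesterol synthesis 19 fell (median -0.85, camera adjusted p = 7.24e-12, and adjusted p = 0.478 with an estimated correlation), with Lss at -1.64 and Mvd at -1.29. Hypoxia and glycolysis genes fell in 16 of 19 cases (median -0.78, camera adjusted p = 1.92e-06, and adjusted p = 0.589 with an estimated correlation), with Vegfa, the endothelial growth factor, at -1.18 and Pgk1 at -0.89. In the Notch pathway 14 of 18 genes fell and 2 rose (median -0.56, camera adjusted p = 5.12e-05, and adjusted p = 0.431 with an estimated correlation). Hes5, a Notch effector that maintains progenitors, fell to -2.24 and Hey2 to -1.91, whereas the ligand Jag1 rose by 1.33. Intermediate progenitor genes fell in 8 of 12 cases (median -0.53, camera adjusted p = 0.0101, and adjusted p = 0.431 with an estimated correlation), with the proneural factor Neurog2 at -1.95. Neurog2 stood low, going from 1.78 ± 1.20 to 0.449 ± 0.265 CPM (SD, n = 3). Of 11 meningeal and mesenchymal genes 8 rose, among them Col3a1 at 1.34 (camera adjusted p = 0.0185, and adjusted p = 0.589 with an estimated correlation). Col3a1 went from 3.70 ± 3.17 to 9.18 ± 7.66 CPM (SD, n = 3). The last 2 list calls were lost without the culture block (camera adjusted p = 0.0827 and 0.196). Adjusted over the list alone, the counts in these 5 lists were the same, at 19, 16, 14, 8 and 8.

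Over all genes, 11986 of 22222 changed in WT cultures by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6133 higher and 5853 lower, and 2576 of them by more than 2-fold. The largest rises included Kcng4, a potassium channel subunit, at 5.01, the calcium pump Atp2a3 at 4.65, Rgs5 at 4.14, Ddo at 3.77, Palm3 at 3.73, Sgca at 3.71, Lama3 at 3.71 and Ptprv at 3.69. The largest falls included Sbk3 at -3.39, Cdkn1c, an inhibitor of the cell cycle, at -3.11, the tetraspanin Cd82 at -2.96, the growth factor Bmp4 at -2.86, Enpp6 at -2.76, Kif19a at -2.66, Fa2h at -2.59 and Npcd at -2.50. Near Pnky, Pou3f2 fell by 0.55 on the log2 scale (SE 0.04), and of the 15 measured genes of this chromosome 4 neighbourhood 4 rose and 9 fell, with Mms22l, a replication repair gene, at 1.57, Manea at -0.58 and Faxc at -0.58. The neighbourhood list as a whole did not pass camera's test (adjusted p = 0.151).

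In FF cultures, where Ad:Cre acts on the floxed Pnky gene, 8 of these 9 lists passed in the same directions, all but the meningeal list. All 18 S phase genes rose (median 1.93, camera adjusted p = 2.15e-13, and adjusted p = 0.372 with an estimated correlation), as did 18 of 20 G2 and M phase genes (median 0.97, camera adjusted p = 4.62e-05, and adjusted p = 0.711 with an estimated correlation). So did 19 of 20 p53 targets (median 0.74, camera adjusted p = 3.28e-10, and adjusted p = 0.372 with an estimated correlation) and 9 of 14 ERK feedback genes (median 0.28, camera adjusted p = 0.00656, and adjusted p = 0.668 with an estimated correlation). Ccnd1 rose by 2.70, Mcm3 by 2.44, Perp by 2.38 and Dusp6 by 1.36. All 20 cholesterol synthesis genes fell (median -1.01, camera adjusted p = 3.38e-13, and adjusted p = 0.404 with an estimated correlation). With them fell 17 of 19 hypoxia genes (median -1.03, camera adjusted p = 2.81e-08, and adjusted p = 0.668 with an estimated correlation) and 14 of 18 Notch pathway genes (median -0.64, camera adjusted p = 3.20e-05, and adjusted p = 0.372 with an estimated correlation). Lss reached -1.57, Vegfa -1.37 and Hes5 -2.08. Intermediate progenitor genes fell in 8 of 12 cases (median -0.58, camera adjusted p = 0.0131, adjusted p = 0.372 with an estimated correlation, and 0.0966 without the culture block). Adjusted over the list alone, the counts in these 8 lists were 18, 18, 19, 9, 20, 18, 14 and 8. Among 22222 genes 11901 changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5943 higher and 5958 lower, 2446 of them by more than 2-fold. The largest rises were Kcng4 at 5.80, Atp2a3 at 4.34, Ddo at 4.25, Sgca at 3.82, the neurotrophin receptor Ngfr at 3.76, Palm3 at 3.76, Cdc6, which loads the replicative helicase, at 3.72 and Gfap, the intermediate filament of astrocytes, at 3.66. The largest falls besides Pnky were Npcd at -3.21, Cd82 at -2.89, Cdkn1c at -2.83, Mylk3 at -2.77, Sbk3 at -2.62, Rcn3 at -2.54, Ndrg1 at -2.48 and Rasd2 at -2.44. Pou3f2 fell by 0.89 (SE 0.04), from 62.2 to 33.6 CPM, and in its neighbourhood 5 of 15 genes rose and 9 fell.

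BAC cultures, which keep a source of Pnky outside its locus, gave 12380 changed genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6177 higher and 6203 lower, 2825 of them by more than 2-fold. All 18 S phase genes (median 1.93, camera adjusted p = 1.40e-12) and all 20 p53 targets (median 1.11, camera adjusted p = 1.40e-12) rose, each with adjusted p = 0.394 with an estimated correlation. With them rose 18 of 20 G2 and M phase genes (median 0.80, camera adjusted p = 0.00143, and adjusted p = 0.574 with an estimated correlation). The same held for 10 of 14 ERK feedback genes (median 0.35, camera adjusted p = 1.14e-04, and adjusted p = 0.394 with an estimated correlation) and 8 of 11 meningeal genes (median 0.65, camera adjusted p = 0.00984, adjusted p = 0.507 with an estimated correlation, and 0.116 without the culture block). All 20 cholesterol synthesis genes fell (median -0.996, camera adjusted p = 8.81e-13, and adjusted p = 0.394 with an estimated correlation), along with 17 of 19 hypoxia genes (median -1.03, camera adjusted p = 3.64e-07, and adjusted p = 0.574 with an estimated correlation). Falls were also seen in 14 of 18 Notch pathway genes (median -0.65, camera adjusted p = 2.81e-05, and adjusted p = 0.394 with an estimated correlation) and 8 of 12 intermediate progenitor genes (median -0.78, camera adjusted p = 0.00254, and adjusted p = 0.394 with an estimated correlation). The list of splicing regulators holds PTBP, a protein family that represses neuronal exons, and other regulators of neuronal splicing. Of its 18 genes 12 fell and 3 rose (median -0.26, camera adjusted p = 0.0277, and adjusted p = 0.574 with an estimated correlation). Ptbp1 itself did not go with the list, at a mean of 126.9 CPM in untreated BAC cultures and 142.15 CPM after Ad:Cre. The means of Nova1, Khdrbs3 and Elavl3 were lower after Ad:Cre. Perp rose by 2.88, Plk2 by 1.96 and Spry1 by 1.77, and Hes5 fell to -3.26, Hey2 to -2.24 and Mfng, a modifier of Notch receptors, to -2.53. Among the largest rises were Kcng4 at 5.52, Atp2a3 at 4.86, Palm3 at 4.58, Sgca at 4.35, H2-Eb1 at 4.22, Cd55 at 4.22, Ddo at 4.02 and Ngfr at 3.96. The largest falls besides Hes5 and Pnky were Cdkn1c at -3.48, the cardiac actin Actc1 at -3.23, Npcd at -2.91, Cd82 at -2.83, Fa2h at -2.81, Draxin at -2.76 and Synpo2l at -2.76. Pou3f2 fell by 0.77 (SE 0.04). Adjusted over the list alone, the counts in these 10 lists were 18, 20, 18, 10, 8, 20, 17, 14, 9 and 12.

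**Figure D3:**
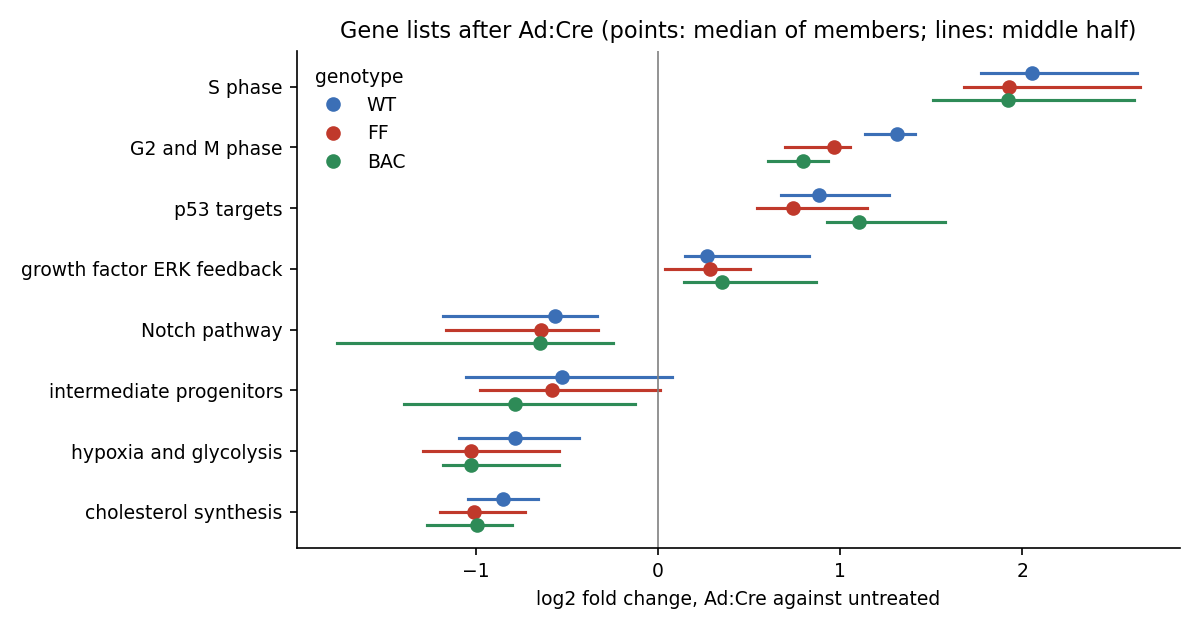
Log2 fold change after Ad:Cre against untreated (horizontal axis) for 8 gene lists in WT, FF and BAC cultures, with points at the median of the list and lines over the middle of its members, from the lower to the upper quartile. S phase medians were 2.05, 1.93 and 1.93 and cholesterol synthesis medians -0.85, -1.01 and -0.996 in WT, FF and BAC.

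The responses of the 3 genotypes lay close together. Between WT and FF the log2 fold changes had a Pearson correlation of 0.75 and a Spearman correlation of 0.80 across 22222 genes, which are not independent replicates. WT and FF shared 5164 rising and 5054 falling genes, where independent lists would share 1640 and 1569, and 11 genes were called in opposite directions. Of the genes called in FF, 98.6% had the same sign in WT and 98.1% in BAC. In all 3 genotypes 9671 genes were called, 4860 of them higher and 4805 lower throughout. No libraries are shared between genotypes here.

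The difference between the Ad:Cre effects of FF and WT cultures asks what loss of Pnky adds to the response to virus and Cre. Higher or lower in such a difference refers to the log2 fold change after Ad:Cre and not to the level. Pnky differed by -5.88 (SE 0.33) and Miat, another long noncoding RNA of the nervous system, by 0.57 (SE 0.07), with adjusted p = 5.81e-06 and 0.0149 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Miat fell in all 3 genotypes, by 1.48 in WT, 0.91 in FF and 1.89 in BAC cultures on the log2 scale. Untreated Miat stood at 200 ± 18.8 CPM in FF and 247 ± 67.9 in WT, and after Ad:Cre at 106 ± 8.45 and 88.5 ± 21.5 (SD, n = 3). Its untreated level thus enters the difference. Pnky and Miat were the only 2 genes of 22222 to pass, with 1917 at an unadjusted p under 0.05, and DESeq2 called 50. Pou3f2 differed by -0.34 (SE 0.06) and did not pass over all genes (adjusted p = 0.122 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). As a gene named before the data were examined, Pou3f2 had an unadjusted p of 9.51e-05 by that edgeR test. Its untreated levels were alike, at 62.2 ± 1.77 CPM in FF and 60.7 ± 2.47 in WT. After Ad:Cre they were 33.6 ± 0.433 and 41.5 ± 2.89 CPM (SD, n = 3). Genes with the smallest p that did not pass were, with a higher effect in FF, Sh3bp4 (0.47), Gfap (0.92), Myrf (0.67), a transcription factor of myelination, Bcas1 (0.68) and its antisense neighbour Bcas1os2 (1.20), and, with a lower effect in FF, Dusp4 (-0.55), Aph1b (-0.37), Rdh16f1 (a fitted -8.04, with 0 CPM in FF after Ad:Cre), Antxr2 (-0.41) and Gpnmb (-0.54). Gfap stood lower in FF than in WT both untreated (7.82 against 21.5 CPM) and after Ad:Cre (99.1 against 138), and Gpnmb differed only untreated (27.9 against 19.1 CPM, and 16.5 against 16.4 after Ad:Cre), so untreated levels enter both values. The Miat call rested on single libraries and settings: it was lost without any 1 of the 3 FF cultures or WT culture 1 (adjusted p = 0.0867, 0.212, 0.106 and 0.135 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), without the culture block and with transcript lengths as an offset (adjusted p = 0.999 and 0.0717). Without WT culture 2 or 3 there were 10 genes each, and with no filter on low counts 481, of which 143 were higher and 338 lower.

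As groups, 9 of 30 lists passed camera's test for the difference in Ad:Cre effect of FF against WT, with no member past the threshold over all genes. Higher in FF were the oligodendrocyte lineage (median 0.14, 3 genes adjusted over the list alone, camera adjusted p = 4.90e-04, and adjusted p = 0.643 with an estimated correlation), with Gpr17 at 0.61 and Sox10 at 0.28. Astrocyte genes were higher too (median 0.06, 2 genes adjusted over the list alone, camera adjusted p = 0.00641, adjusted p = 0.757 with an estimated correlation, and 0.169 without the culture block), although 9 of 12 stood lower in FF than in WT when untreated, with Gfap among them. Lower in FF were G2 and M phase genes (median -0.34, camera adjusted p = 0.00115, and adjusted p = 0.796 with an estimated correlation), whose call was lost without FF culture 1 (adjusted p = 0.102) and whose direction turned without WT culture 3. Lower as well were p53 targets (-0.12, camera adjusted p = 3.12e-04, and adjusted p = 0.757 with an estimated correlation) and immediate early genes (-0.30, 4 adjusted over the list alone, camera adjusted p = 0.00105, and adjusted p = 0.643 with an estimated correlation), among them Nr4a1 at -0.50, which differed in untreated level (20.9 against 14.7 CPM) and not after Ad:Cre (10.3 in both), and Arc at -0.49. ERK feedback genes (-0.14, 5 adjusted over the list alone, camera adjusted p = 2.70e-04, and adjusted p = 0.643 with an estimated correlation) and hypoxia genes (-0.18, camera adjusted p = 1.77e-04, and adjusted p = 0.757 with an estimated correlation) followed. The same direction was found for cholesterol synthesis genes (-0.11, 1 adjusted over the list alone, camera adjusted p = 4.53e-04, and adjusted p = 0.757 with an estimated correlation) and stress response genes (-0.13, 3 adjusted over the list alone, camera adjusted p = 1.77e-04, and adjusted p = 0.643 with an estimated correlation). In the 3 lists with no count given, 0 genes passed when adjusted over the list alone.

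FF and BAC cultures share the floxed alleles and differ in the transgene, so the difference of their Ad:Cre effects asks what the transgene changes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 374 of 22222 genes differed, 196 higher and 178 lower in FF, with Miat at the smallest adjusted p (0.98, adjusted p = 6.13e-05). The p53 targets were the clearest group. Of 20, 12 were lower in FF, and 19 adjusted over the list alone, with Pmaip1 at -0.56, Cdkn1a, the cell cycle inhibitor p21, at -0.48, Plk2 at -0.47 and Phlda3 at -0.42 (median -0.39, camera adjusted p = 3.75e-21, and adjusted p = 0.144 with an estimated correlation). ERK feedback genes were lower in 4 of 14 cases, 10 adjusted over the list alone, with Dusp4 at -0.63, Spry1 at -0.62, Dusp6 at -0.41 and Etv5 at -0.32 (median -0.20, camera adjusted p = 8.82e-09, and adjusted p = 0.160 with an estimated correlation). Genes of the oligodendrocyte lineage were higher in FF in 4 of 11 cases, 6 adjusted over the list alone, with Gpr17 at 1.12, Sox10 at 0.60, Lhfpl3 at 0.60 and Sox8 at 0.37 (median 0.37, camera adjusted p = 2.53e-07, and adjusted p = 0.144 with an estimated correlation). Notch pathway genes were higher in 4 of 18 cases, 6 adjusted over the list alone, namely Hes5 at 1.18, Mfng at 1.08 and the ligands Dll3 at 0.89 and Dll1 at 0.55 (median 0.08, camera adjusted p = 5.23e-04, and adjusted p = 0.381 with an estimated correlation). The last 3 also belong to the intermediate progenitor list, of which 3 of 12 were higher, 4 adjusted over the list alone (median 0.26, camera adjusted p = 1.88e-05, and adjusted p = 0.160 with an estimated correlation).

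The other 6 lists that passed for FF against BAC had fewer passing members. Astrocyte genes were higher (2 of 12, Aldoc and Fgfr3 at 0.58 and 0.44, 4 adjusted over the list alone, camera adjusted p = 0.0315, and adjusted p = 0.605 with an estimated correlation), as were cholesterol synthesis genes (1 of 20, Mvk at 0.32, 2 adjusted over the list alone, camera adjusted p = 0.00215, and adjusted p = 0.692 with an estimated correlation). Immediate early genes were lower (1 of 17, Arc at -0.81, 6 adjusted over the list alone, camera adjusted p = 6.90e-04, and adjusted p = 0.315 with an estimated correlation). Interferon response genes were lower in 3 of 24 cases, H2-K1 at -0.35, H2-D1 at -0.29 and B2m at -0.25, which together form class I histocompatibility molecules (4 adjusted over the list alone, camera adjusted p = 0.0158, and adjusted p = 0.521 with an estimated correlation). Stress response genes were lower in 2 of 20 cases, Sesn2 at -0.28 and the amino acid transporter Slc7a5 at -0.27 (3 adjusted over the list alone, camera adjusted p = 0.0224, and adjusted p = 0.521 with an estimated correlation). Meningeal genes were lower with 0 of 11 past the threshold and 1 adjusted over the list alone (median -0.26, camera adjusted p = 0.0146, and adjusted p = 0.521 with an estimated correlation). Without the culture block the astrocyte, interferon and meningeal calls were lost (adjusted p = 0.141, 0.0865 and 0.0767). Among the genes of largest difference were Actc1 at 1.15 and Bmp4 at 1.05, higher in FF, and Golga7b at -0.997, Zbtb7c at -0.77 and Crispld2 at -0.75, lower in FF. Pnky differed by -3.62, and Pou3f2 by -0.11 without passing (adjusted p = 0.464 by the same edgeR test with Benjamini-Hochberg adjustment). Without the culture block 13 genes passed. Leaving out any 1 of the 6 cultures lowered the count by more than 1.5 times, to between 110 (without FF culture 1) and 249 (without BAC culture 1), and DESeq2 called 604.

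**Figure D4:**
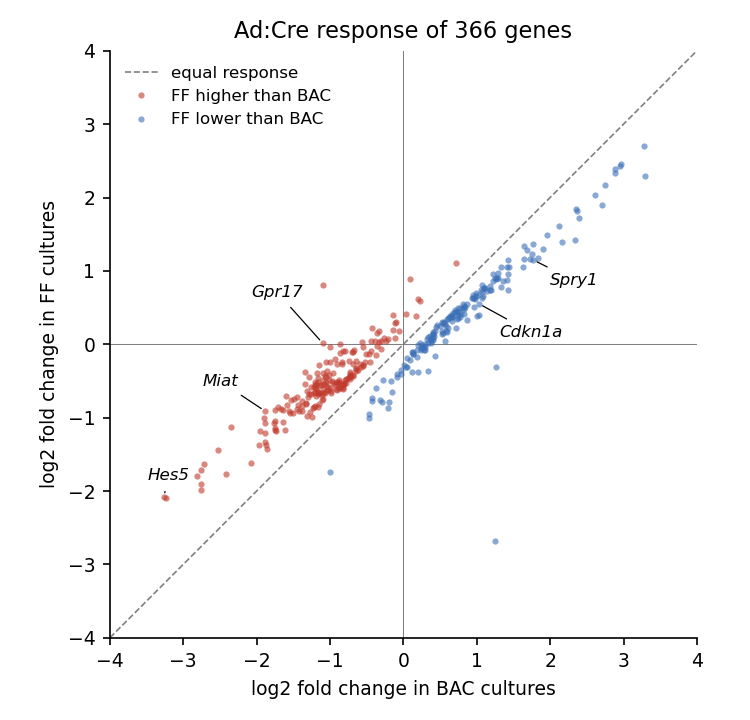
Log2 fold change after Ad:Cre in FF cultures (vertical axis) against that in BAC cultures (horizontal axis) for the genes whose Ad:Cre effect differed between them, with a dashed line where both responses are equal. Of 373 genes without Pnky 366 lie within the axes, and the genes higher in FF had medians of -0.54 in FF, -1.06 in BAC and -0.71 in WT.

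The difference between BAC and WT cultures concerned 12 genes, 3 higher and 9 lower in BAC, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 2137 genes at an unadjusted p under 0.05. Besides Pnky (-2.26, SE 0.23, adjusted p = 0.00548), the lower genes included Hes5 (-1.02), Mfng (-0.81), Sema3d (-0.76), a guidance cue, Dll3 (-0.56) and Prkcq (-0.47), and the higher ones were mt-Co2 (0.56), a mitochondrially encoded subunit of cytochrome oxidase, Spry1 (0.43) and Gsta4 (0.35). These 3 genes started from lower untreated levels in BAC, at 1196 ± 311 CPM in BAC against 2702 ± 760 in WT for mt-Co2, 46.6 ± 0.804 against 60.9 ± 0.740 for Spry1 and 68.8 ± 4.98 against 88.8 ± 6.48 for Gsta4 (SD, n = 3). After Ad:Cre mt-Co2 was still lower in BAC (1995 ± 538 against 3053 ± 841), and Spry1 and Gsta4 lay close together (159 against 154 and 100 against 101). Pou3f2 differed by -0.22 and did not pass over all genes (adjusted p = 0.231 by the same edgeR test with Benjamini-Hochberg adjustment). Its unadjusted p by that test was 0.0027. After Ad:Cre Pou3f2 stood at 36.6 ± 1.29 CPM in BAC and 41.5 ± 2.89 in WT (SD, n = 3). In 10 of 30 lists camera's test passed. The p53 targets were higher in BAC (14 of 20 adjusted over the list alone, median 0.27, camera adjusted p = 4.17e-17, and adjusted p = 0.235 with an estimated correlation), as were ERK feedback genes (2 adjusted over the list alone, median 0.08, camera adjusted p = 1.85e-04, and adjusted p = 0.413 with an estimated correlation). Cholesterol synthesis genes (9 adjusted over the list alone, median -0.19, camera adjusted p = 1.05e-12, and adjusted p = 0.413 with an estimated correlation) were lower. So were G2 and M phase genes (-0.49, camera adjusted p = 4.43e-07, and adjusted p = 0.532 with an estimated correlation) and hypoxia genes (-0.13, camera adjusted p = 0.00267, and adjusted p = 0.746 with an estimated correlation). Notch pathway genes (3 of 18, 6 adjusted over the list alone, median -0.15, camera adjusted p = 2.59e-06), intermediate progenitor genes (2 of 12, 4 adjusted over the list alone, -0.24, 3.52e-06) and oligodendrocyte lineage genes (6 adjusted over the list alone, -0.23, 2.45e-04) were lower too, each with adjusted p = 0.235 with an estimated correlation. Splicing regulators (-0.09, camera adjusted p = 0.00982) and radial glia genes (1 of 20, Hes5, median -0.05, camera adjusted p = 0.0457, and 0.0902 without the culture block) had adjusted p = 0.532 with an estimated correlation. The hypoxia call was lost and its direction turned without WT culture 3 (adjusted p = 0.642). The Pnky call itself was lost without WT culture 2 (-2.16) or BAC culture 1 (-2.20), where 0 genes passed. The count was 39 without WT culture 1, 29 without WT culture 3 and 3 without BAC culture 2. Without the culture block, or with transcript lengths as an offset, 1 gene passed. With sex by Ad:Cre as a covariate, added because 2 of 3 WT and 1 of 3 BAC cultures were female, 4 genes passed. Without sex in the fit DESeq2 called 152, and edgeR with no filter on low counts 653.

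Untreated cultures were compared to ask whether the genotypes differed before Ad:Cre. Dhtkd1, a mitochondrial dehydrogenase subunit, was higher in FF than in WT, at 33.8 ± 8.41 against 15.8 ± 2.57 CPM (n = 3 each), a log2 difference of 1.10 (SE 0.15) with adjusted p = 0.0342 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was the only gene of 22222 to pass, with 1944 at an unadjusted p under 0.05, and 69 called by DESeq2. The Dhtkd1 call was lost without untreated WT culture 1 or 2 (adjusted p = 0.230 and 0.197 by the same edgeR test with Benjamini-Hochberg adjustment) and with sex as a covariate (adjusted p = 0.0507). With transcript lengths as an offset its log2 difference was 0.51 (adjusted p = 0.422). The count of genes was 2 without untreated FF culture 3, 0 without WT culture 2 and 3 without WT culture 3. Pnky (-0.017) and Pou3f2 (0.035) did not pass. Not passing with the smallest p were Sik1 (0.45), Klhdc8b (0.64), Nr4a1 (0.51), Rpl10 (0.26) and Cybrd1 (0.82), higher in FF, and Tpbg (-0.70), Zfp950 (-0.31), Vps13c (-0.23), Gsta4 (-0.29) and Phf11c (-1.12), lower in FF. In 4 lists FF was higher, namely stress response (median 0.15, 4 genes adjusted over the list alone, camera adjusted p = 6.28e-06, and adjusted p = 0.181 with an estimated correlation), hypoxia (0.19, camera adjusted p = 8.43e-06, and adjusted p = 0.918 with an estimated correlation), cholesterol synthesis (0.12, camera adjusted p = 4.85e-05, and adjusted p = 0.918 with an estimated correlation) and immediate early genes (0.22, 4 adjusted over the list alone, camera adjusted p = 5.93e-04, and adjusted p = 0.181 with an estimated correlation). The untreated libraries enter the differences of Ad:Cre effects with the opposite sign, so part of the mirrored list directions in FF against WT is built in.

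Between untreated BAC and FF cultures 0 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.291), with 1062 genes at an unadjusted p under 0.05, and DESeq2 called 8. Pnky differed by 0.071 and Pou3f2 by 0.0068, neither of them passing. Among the smallest p values that did not pass were those of Rspo4os (0.83), Mylk (0.80), Kcne1l (0.35), Pnpla6 (0.22) and AU020206 (0.24), higher in BAC, and of Arc (-0.61), Spry1 (-0.33), Txndc2 (-4.27, at 0.00428 CPM in BAC) and Morc4 (-0.41), lower in BAC. Astrocyte genes were higher in BAC (median 0.16, camera adjusted p = 3.03e-04) and p53 targets lower (median -0.14, camera adjusted p = 4.85e-07, 1 gene adjusted over the list alone), both with adjusted p = 0.386 with an estimated correlation. These untreated differences enter the FF against BAC differences of Ad:Cre effects, so part of those in Arc, Spry1, p53 targets and astrocyte genes is built in. After Ad:Cre Arc stood at 4.72 CPM in FF and 5.44 in BAC, and Spry1 at 130 and 159.

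The cortex and FF culture comparisons had 0 called genes in common among 16115 tested in both, since edgeR's quasi-likelihood test called 0 in the cortex, where DESeq2 called 20. Their log2 fold changes had a Pearson correlation of 0.04 and a Spearman correlation of 0.07 across genes. For the cortex and WT cultures, which carry no floxed allele, these were 0.06 and 0.10, and for the cortex and the difference of FF against WT -0.05 and -0.11.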

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

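Of the tests in this part, all but that on the sex of the embryos were chosen after the results were seen, and its fit with sex was added after the data were seen. The results below were singled out because the Ad:Cre effect differed between 2 genotypes by the test of the difference itself (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). For FF against WT these were 2 genes, Pnky at -5.88 and Miat at 0.57.

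For FF against BAC there were 374 genes. Higher in FF were Hes5 (1.18), Actc1 (1.15), Gpr17 (1.12), Mfng (1.08), Bmp4 (1.05), Dll3 (0.89), Sox10 (0.60), Lhfpl3 (0.60), Aldoc (0.58), Dll1 (0.55), Fgfr3 (0.44), Sox8 (0.37) and Mvk (0.32). Lower in FF were Pnky (-3.62), Golga7b (-0.997), Arc (-0.81), Zbtb7c (-0.77), Crispld2 (-0.75), Dusp4 (-0.63), Spry1 (-0.62), Pmaip1 (-0.56), Cdkn1a (-0.48), Plk2 (-0.47), Phlda3 (-0.42), Dusp6 (-0.41), H2-K1 (-0.35), Etv5 (-0.32), H2-D1 (-0.29), Sesn2 (-0.28), Slc7a5 (-0.27) and B2m (-0.25). Untreated levels enter these differences, since untreated Arc and Spry1 already differed by -0.61 and -0.33 between BAC and FF.

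For BAC against WT there were 12 genes, among them mt-Co2 (0.56), Spry1 (0.43) and Gsta4 (0.35), higher in BAC, and Pnky (-2.26), Hes5 (-1.02), Mfng (-0.81), Sema3d (-0.76), Dll3 (-0.56) and Prkcq (-0.47), lower in BAC. Differences between untreated levels enter those of mt-Co2, Spry1 and Gsta4, as the report gives.

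The difference between FF and BAC cultures is the pattern a biologist may want to follow, since the transgene carries Pnky. Uninfected cells as the source of a weaker FF response are argued against by Pnky itself, which stood at 1.02% of untreated in FF cultures after Ad:Cre, whereas a diluted response would leave Pnky in the uninfected share. The level of Pnky as the whole cause is argued against by WT cultures, which kept the most Pnky. Genes were chosen without the FF and BAC cultures of 1 number. In these held-out cultures the genes differed less between FF and the mean of all 3 WT cultures than between FF and BAC. The ratios were 0.312, 0.446 and at most 0.543. No WT culture was held out, so the 2 sides of each ratio are built unlike, and WT cultures also differ from the others in sex. A weaker shared response in FF than in BAC cultures, or a stronger one in BAC, stays open for part of the response. Of the 373 genes without Pnky, all chosen for differing between FF and BAC, 87.4% differed against the direction of the WT response. List medians were weaker in FF for p53 targets (0.74 against 1.11), ERK feedback (0.28 against 0.35) and intermediate progenitors (-0.58 against -0.78). They were alike for S phase (1.93 in both), hypoxia (-1.03 in both) and cholesterol synthesis (-1.01 and -0.996). For G2 and M phase the median was larger in FF (0.97 against 0.80). A response weaker in FF throughout was thus not seen. Whether such a difference in strength follows infection, culture or genotype was not tested.

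Microglia genes higher in cKO cortex are the other pattern. More endothelial, mural, meningeal or erythroid cells in the cKO dissections of litters 2 and 5 are argued against. The highest median of these lists there was 0.0437, beside microglia medians of 0.49 and 0.82. Surface ectoderm genes, with a median of 0.42 and a mean of 0.07 over all litters, were not tested by litter. More skin in the cKO dissections was thus not excluded. In litter 1 more non-neural cells cannot be told apart from a rise in microglia alone, because in this single pair of embryos erythroid genes had a median of 0.535 and endothelium genes one of 0.244, while those of meningeal and mural genes were 0.101 and 7.03e-04, beside a microglia median of 0.55. The sex of the embryos cannot be told apart from genotype, because only litter 2 had embryos of equal sex, with a microglia median of 0.490, and the median over all libraries was 0.73 with sex in the fit against 0.78 without. A change in microglia number or state in the cKO embryos may also stay open, untested.

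Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. In the cortex the real split called 0 genes and the highest other 20, and all 10 splits called at least as many as the real one. That split does not part every litter, and the cause of its calls was not tested. The other splits that part every litter called 1, 0 and 0 genes. In the cultures the real splits called 11986 (WT), 11901 (FF), 12380 (BAC), 2 (FF against WT), 374 (FF against BAC), 12 (BAC against WT) and 1 (untreated FF against WT) genes. In each of these 7 the highest other split called 0, so that 1 split was as high as the real one, but within WT, FF and BAC cultures a split that mixes treated and untreated libraries inflates the spread and so makes 0 close to built in. Between untreated BAC and FF cultures the real split and the highest other called 0, and 10 of 10 splits were as high.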

How the results depend on the processing

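Sex as a covariate was the alternative chosen after the data were seen. The cause of a change was not tested unless stated. With an estimated correlation 0 lists passed in each of the 9 comparisons. Counts of changed genes within WT, FF and BAC cultures stayed within 1.5 times under every alternative. The other scaling, by the size factors of DESeq2, moved medians over all genes by at most 0.02. Like TMM it takes most genes as unchanged, so this does not test for a shift shared by most genes.

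With no filter on low counts edgeR called 7 genes in cortex, 481 for FF against WT (143 higher and 338 lower), 1044 for FF against BAC, of which 372 were among the 374, 653 for BAC against WT, 11 for untreated FF against WT and 1 for untreated BAC against FF. With the size factors of DESeq2 within edgeR the share of higher genes among the calls for FF against BAC was 47.8%, against 52.4% with TMM, and within BAC cultures 50.7% against 49.9%. For FF against WT it was 33.3% of 3 calls, against 50% of 2. DESeq2 as the test called 20, 50, 604 (357 shared), 152, 69 and 8 in the same order. With transcript lengths as an offset 1 gene passed for FF against WT, 191 for FF against BAC (176 shared) and 1 for BAC against WT. Sex as a covariate left 4 genes for BAC against WT and 0 for untreated FF against WT.

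For the block by litter or culture, DESeq2 with the block called 12 genes in cortex and edgeR with it 0. Without the culture block 1 gene passed for FF against WT, 13 for FF against BAC (13 shared) and 1 for BAC against WT. A replicate block on the number alone gave 5 for untreated FF against WT, where samples of the same number correlated little. List calls that changed with the block stand beside the lists, and the block moved no other count of genes by more than 1.5 times.

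Leaving out each library in turn gave 0 to 7 genes in cortex (7 without control 2), 1 to 10 for FF against WT (10 without WT 2 or WT 3), 110 to 249 for FF against BAC (without FF 1 and BAC 1), 0 to 39 for BAC against WT (0 without WT 2 or BAC 1, 39 without WT 1) and 0 to 3 for untreated FF against WT. Pnky ran from -2.43 to -2.15 for BAC against WT, with its call lost at -2.16 and -2.20, from -0.0684 to 0.0833 for untreated FF against WT and from -0.0755 to 0.159 for untreated BAC against FF, and Pou3f2 from -0.0360 to 0.0266 in the last. Passing lists numbered 6 to 17 in cortex (17 without control 1) and 6 to 13 for BAC against WT (6 without WT 3). The list adjusted p ran from 1.09e-06 to 0.371 for erythroid genes in cortex, from 8.27e-10 to 0.102 for G2 and M phase in FF against WT (0.102 without FF 1, 0.0300 without WT 3, where the direction turned) and from 2.10e-06 to 0.642 for hypoxia in BAC against WT.

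Of all alternatives run, named genes kept direction and call in 4475 cases, lost the call in 287, gained it in 63 and turned in 2. For lists 362 calls held, 114 were lost and 3 turned. Pnky had 45 to 103 counts per library in the cortex.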

Other observations

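Other cell type and pathway lists did not pass as groups after Ad:Cre in cultures, while single members rose or fell. Among 12 astrocyte genes 7 rose and 4 fell in each genotype, with Gfap at 2.74 (SE 0.10) in WT, 3.66 in FF and 3.26 in BAC, and S100b, a calcium-binding protein of astrocytes, at 1.55, 1.75 and 1.56, while Fgfr3 fell to -1.13, -1.17 and -1.61 (n = 3 against 3 cultures each, camera adjusted p = 0.290, 0.201 and 0.236). Oligodendrocyte lineage genes split into Olig1, which rose by 0.71, 0.73 and 0.74, and Sox10 and Sox8, which fell to -1.06, -0.78 and -1.38 and to -0.99, -0.85 and -1.22 (camera adjusted p = 0.172, 0.541 and 0.163). In the radial glia list Nes, an intermediate filament of neural stem cells, rose by 1.20, 1.06 and 1.34 and Pax6, a transcription factor of dorsal progenitors, fell to -0.56, -0.63 and -0.70 (camera adjusted p = 0.337, 0.201 and 0.189). Among 18 genes of postmitotic neurons 3, 4 and 4 rose and 9, 7 and 9 fell, with Mapt, the tau gene, at -1.07, -0.97 and -1.30 and Gap43 at 1.01, 0.86 and 1.11 (camera adjusted p = 0.151, 0.257 and 0.199). Interferon response genes rose in 11, 11 and 17 of 24 cases and fell in 6, 5 and 5, with Ifi35 at 1.02, 0.97 and 1.03 (camera adjusted p = 0.151, 0.325 and 0.0595). Immediate early genes rose in 12, 7 and 12 of 17 cases and fell in 4, 4 and 4, with Arc at 2.39, 1.90 and 2.71 (camera adjusted p = 0.101, 0.536 and 0.0855). Stress response genes rose in 10, 8 and 9 of 20 cases and fell in 4, 7 and 4, with the chaperone Hspa5 at 0.75, 0.76 and 0.76 (camera adjusted p = 0.151, 0.60 and 0.229).

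Mitochondrially encoded transcripts, a group chosen after their values were seen, rose after Ad:Cre. Of 13 protein-coding genes of the mitochondrial genome 12 rose in WT, 12 in FF and 11 in BAC cultures, with median log2 fold changes of 0.54, 0.62 and 0.62. Their share of all counts went from 5.99 ± 0.148 to 7.30 ± 0.445% in WT, from 5.75 ± 0.427 to 7.28 ± 0.384% in FF and from 5.63 ± 0.336 to 7.30 ± 0.444% in BAC (SD, n = 3).

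The remaining lists did not pass in cultures. In the order WT, FF and BAC, camera adjusted p was 0.151, 0.190 and 0.111 for deep-layer neurons, 0.408, 0.370 and 0.262 for upper-layer neurons, 0.977, 0.977 and 0.736 for Cajal-Retzius and subplate neurons, 0.423, 0.501 and 0.257 for the subpallial lineage and 0.934, 0.766 and 0.969 for the cortical hem and choroid plexus. For other cell types it was 0.681, 0.766 and 0.489 for endothelium, 0.420, 0.550 and 0.238 for mural cells, although the mural marker Rgs5 rose by 4.14, 3.53 and 3.82, and 0.151, 0.157 and 0.257 for microglia, although P2ry12 rose by 3.26, 3.15 and 2.92. Both of these markers stood low, Rgs5 going from 0.230 to 4.07 CPM and P2ry12 from 0.298 to 2.78 CPM in WT cultures. Camera adjusted p was 0.420, 0.541 and 0.460 for Wnt targets, 0.420, 0.550 and 0.625 for Hedgehog targets, 0.420, 0.550 and 0.356 for axon guidance and 0.420, 0.766 and 0.888 for sex-linked genes. Splicing regulators in WT and FF had 0.101 and 0.0808, the chromosome 4 neighbourhood in FF and BAC 0.236 and 0.228, and meningeal genes in FF 0.190, with 7 of 11 rising. Erythroid and surface ectoderm lists had too few measured genes in cultures, 3 and 4. In the cortex the lists not named above had camera adjusted p of 0.203 for Cajal-Retzius and subplate neurons, 0.358 for astrocytes, 0.988 for the oligodendrocyte lineage, 0.539 for endothelium, 0.955 for mural cells, 0.820 for meninges, 0.0557 for G2 and M phase, 0.910 for the interferon response, 0.411 for immediate early genes, 0.789 for Hedgehog targets, 0.420 for ERK feedback, 0.236 for hypoxia, 0.955 for cholesterol synthesis, 0.358 for the stress response, 0.986 for axon guidance and 0.789 for splicing regulators. Of the sex-linked genes 1 was tested there, with a log2 difference of 1.62.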
